A study of Rattus norvegicus with 3 samples.

How the data were processed

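RNA was extracted from extracellular vesicles of cultured rat adipose-derived mesenchymal stem cells, in 3 libraries of 1 group. Per the labels' protocols, libraries were made with a stranded total RNA kit for low input that primes reverse transcription along the RNA, and cDNA of ribosomal RNA was then cut with probes before a further round of PCR. Sequencing was paired-end on an Illumina NovaSeq. RNA was purified with a column kit that is sold with a column for removing genomic DNA, and the protocol names no DNase step. It names no molecular identifiers, so duplicate reads are not independent molecules and counting intervals cover counting error only. Removal of ribosomal cDNA makes the level of ribosomal RNA genes a remainder, not the content of the vesicles.

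Per the submitters' processing notes, reads were processed with cutadapt 1.9 and FastQC, and the genome build was mRatBN7.2. The aligner, the counting tool and their treatment of reads with several matches and of strand are not given in the sources used here. Reads from genes with related copies (7SL, small nuclear RNA, ribosomal RNA and ribosomal protein genes and their pseudogenes) and from overlapping genes are therefore of uncertain origin. Per the file headers, the deposited table holds gene counts and FPKM for each library with Ensembl gene identifiers, coordinates, biotypes and GO, KEGG and Reactome terms. The counts are whole numbers that the authors did not normalize. The authors' FPKM divides counts by length and by a total per library, and the counts in the table came to 65.4% to 70.7% of the total that the FPKM of mitochondrial genes implies. Genes with 0 counts in all 3 libraries are not among the 29684 rows, since the smallest sum over the libraries is 1. A mean FPKM column of the authors was not used. In 1 gene the start position held no number. Coordinates are those of the table. The depth was 5219920 counts in replicate 1, 6786182 in replicate 2 and 6618461 in replicate 3, and the median gene had 76, 79 and 86 counts. Whole-library read totals were not used here.

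From these values, means and SD over the 3 libraries were computed for genes and classes. A gene was counted as detected at an FPKM of at least 1. Before the data were examined, 38 gene lists were fixed, and 35 had at least 3 measured members; structural RNAs matched 2 genes by symbol, and 0 symbols of the lists of nuclear-retained long non-coding RNAs and of small nucleolar RNA host genes matched. For each list the median log2(FPKM + 1) was set against 10000 random lists of the same size from the 25564 genes with a symbol. A list was called high above the 97.5th percentile and low below the 2.5th in every library. Random lists were not matched on expression, since the level was the quantity of interest. Differences between 10 pairs of lists were taken within each library, with an exact two-sided sign-flip permutation test whose smallest p is 0.25, and set against random pairs. A difference is on the log2 scale with a pseudocount of 1, which understates the change of low genes. Terms with 10 to 500 genes were tested by a one-sided Fisher's exact test among 22882 genes with a term, with Benjamini-Hochberg adjustment.

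The test against the background was added after the distributions of the receptor genes had been seen, and so was its threshold. In each library log2(FPKM + 1) was taken relative to the log2 of the median receptor gene FPKM plus 1, and limma's treat function tested whether the mean over the libraries differed by over 2, that is 4-fold in FPKM + 1 and 5.14-fold in FPKM, with Benjamini-Hochberg adjustment. A gene at 0 in every library differs by -1.87, so only genes above the background could be called. The prior variance was allowed to follow the mean level, without the robust option, which was the form fitted first. Of the 4 forms tried, this form called the most genes: 528, of which 352 were nuclear protein-coding, against 360 (221) with the robust option, 442 (286) with a single prior variance and 420 (267) with a robust single one. On simulated data the forms could not be ranked, since each called 32 of 29484 background genes and 94% to 96% of genes raised 16-fold. The form fitted first was kept for that reason, and its count is the upper end of the range. All simulated genes shared a single dispersion, so those data gave little ground for choosing between the forms. A prior that follows the level widens the error of the highest genes, as for the 7SL copy on chromosome 8 (SE 1.70, adjusted p 0.0423, limma). Of the 352 genes, 71 have symbols of uncharacterised loci or pseudogenes.

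Simulated data were drawn for all 29684 genes around the receptor median with the spread of the receptor genes' means, and 200 genes were set at a fixed fold of the median. Every gene had the same dispersion, 0.05, and no group of genes was shifted between libraries. Genes set at 4-fold lay 1.67 above it on the tested scale, under the threshold, so they could not count as missed. Of genes over the threshold the reported form recovered 2% at 8-fold, 96% at 16-fold and 100% at 32-fold, so a gene that was not called is not shown to be absent. In the measured data the median SD of log2(FPKM + 1) was 0.41 at a mean FPKM of at least 100 and 0.30 over all genes. The recovered shares may therefore not hold for measured genes. Of the 131 genes it called, 99 had been raised and 32 came from the receptor spread. All 32 were drawn at over 4-fold on the tested scale, so they are not false calls of the test, but they are background genes by design. Their share of the 131 depends on the 200 genes set, so it does not carry over to the measured data. Of 200 lists of random genes 0 were called, and 200 of 200 lists raised 4-fold were. Shuffled gene values gave 0 enriched terms, and a planted term was recovered.

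Named genes followed a rule fixed before the data were examined. It took the 15 genes of highest mean FPKM, the 10 highest outside the mitochondrial, ribosomal protein, histone and structural RNA classes, the 4 highest of each list with every member of the mesenchymal, haematopoietic and ovarian lists, the 5 genes of largest spread at a mean FPKM of at least 10, and the 5 highest long non-coding RNA genes. The 15, the 10 and the 5 of largest spread were taken among genes with a symbol. Not every gene that the rule takes is reported here. Hnrnpu and the genes of the hypothesis lists were named after their values had been seen. Alternatives covered pseudocounts of 0.1 and 0.01, rescaling to a common total with and without structural and mitochondrial RNA, filters on low values, counts in place of FPKM, other random lists and leaving out each library. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.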

Results

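The libraries held RNA from extracellular vesicles, the membrane-bound particles that cells release, collected from the medium of cultured rat adipose-derived mesenchymal stem cells. These are multipotent stromal cells, here taken from inguinal fat. There was 1 group of 3 libraries, labelled replicates 1 to 3, each from a batch of vesicles. The stated purpose was to look for RNA components of the vesicles that could be active, in a study of premature ovarian insufficiency. With 1 group there was no treatment contrast, so the comparisons below are between genes and gene groups within the same libraries. Nothing in the labels says that the batches came from separate animals or cultures, and the spread between libraries can be technical. The deposited gene counts summed to 5219920, 6786182 and 6618461 in replicates 1, 2 and 3. Values are the authors' FPKM as mean ± SD over the 3 libraries unless another unit is named.

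By FPKM, genes of structural RNAs had the highest levels. Genes named for 7SL RNA, the RNA of the signal recognition particle that directs secretory proteins to the endoplasmic reticulum, held 27.2% ± 2.19 (SD, n = 3) of the summed FPKM. The mitochondrial genome held 10.3% ± 1.21 (SD, n = 3), nuclear ribosomal RNA genes 6.498% ± 0.889 and cytosolic ribosomal protein genes 2.63% ± 0.714. Nuclear protein-coding genes held 43.2% ± 0.167 of the summed FPKM. The 352 of them called above the receptor background, as described below, held 11.5% ± 2.56 of the summed FPKM and 16.5% ± 3.45 of the counts. Their FPKM share was 8.65%, 13.6% and 12.2% in replicates 1, 2 and 3. A 7SL copy (ENSRNOG00000055825) on chromosome 8 from 58852911 to 58853190 had 41746 ± 4180 FPKM, and Rn7sl1 (ENSRNOG00000065968) on chromosome 6 from 87636804 to 87637103 had 31566 ± 5385. The ribosomal RNA gene LOC120093067 (ENSRNOG00000064743, chromosome 3, 2235683 to 2240483) had 21143 ± 3375 FPKM, in libraries from which ribosomal cDNA had been removed. The vault RNA gene (ENSRNOG00000052373, chromosome 18, 28417454 to 28417597), whose RNA is part of the cytoplasmic vault particle, had 6003 ± 1792 FPKM. Rpph1, the RNA of ribonuclease P, had 1548 ± 283. FPKM divides by length and so weights short RNAs: of the counts, 7SL-named genes held 4.66% ± 0.469, nuclear ribosomal RNA genes 15.02% ± 1.91, the mitochondrial genome 2.95% ± 0.163 and nuclear protein-coding genes 71.3% ± 1.37. The 27 genes named for 7SL RNA can share reads, and their sequence identity was not tested, so the level of any single copy is uncertain.

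Among genes with a symbol outside the mitochondrial, ribosomal protein, histone and structural RNA classes, the most abundant mRNA was Ncl, which encodes the nucleolar RNA-binding protein nucleolin (ENSRNOG00000018273, chromosome 9, 86998019 to 87008136), at 2217 ± 760 FPKM (SD, n = 3). Anp32b, encoding an acidic nuclear phosphoprotein (ENSRNOG00000009266, chromosome 5, 60743443 to 60765717), followed at 1751 ± 552. Kif1c, a kinesin motor (ENSRNOG00000031364, chromosome 10, 55415900 to 55443545), had 1265 ± 296 FPKM. Tpm4, an actin-binding tropomyosin, had 838 ± 240, and Eif3a, a subunit of a translation initiation factor, had 778 ± 243. The small GTPase gene Rab13 had 729 ± 203 FPKM, Arhgap11a 645.0 ± 206 and Kctd10 613 ± 182. LOC100911361 had 531 ± 136 and Zc3h13, a zinc finger protein gene of the RNA methylation machinery, 514 ± 177. After leaving out the mitochondrial genome and structural RNA only, which keeps ribosomal protein genes, the 10 highest genes held 5.04% ± 1.35 of the remaining summed FPKM. Each of the 10 mRNAs named here was lower in replicate 1 than in replicates 2 and 3.

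**Figure D1:**
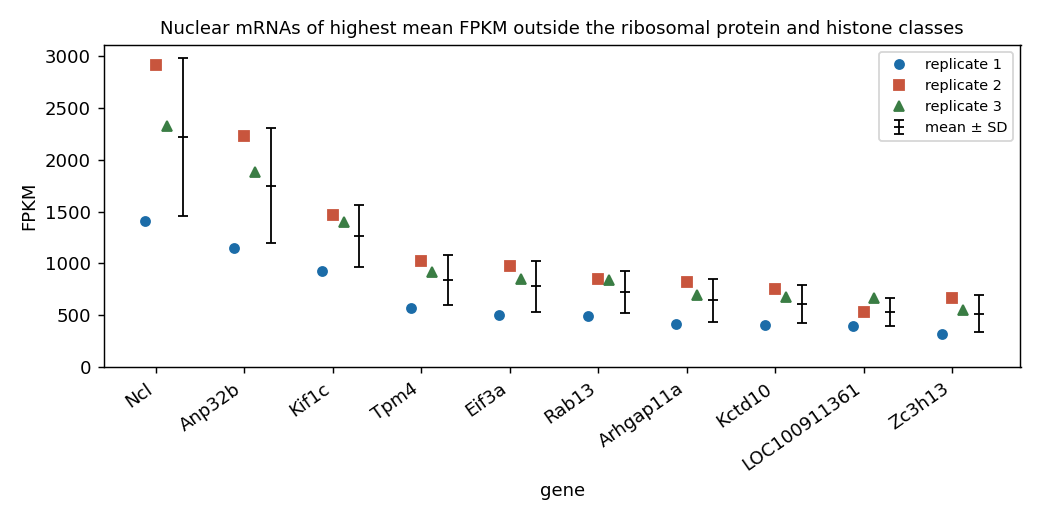
FPKM of the 10 most abundant nuclear mRNAs with a gene symbol outside the ribosomal protein and histone classes, by gene on the x axis, with 1 point per library and the mean ± SD (n = 3) beside it. Ncl had the highest mean, 2217 FPKM, Zc3h13 the lowest of the 10, 514 FPKM, and the point of replicate 1 is the lowest for each gene.

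Most annotated genes had reads at a low and similar level. At an FPKM of at least 1 in every library, 24857 of 29684 genes (83.7%) were counted as detected, and so were 969 of 1390 olfactory and vomeronasal receptor genes (69.7%), which encode chemosensory receptors of the nose. The median receptor gene had 2.67 ± 0.305 FPKM (SD, n = 3) and 43, 39 and 46 counts in replicates 1, 2 and 3. For nuclear protein-coding genes the median was 4.83 ± 0.380 FPKM. The mean of the library medians of coding genes lay between 4.24 and 5.61 FPKM on the 20 autosomes and was 4.05 on chromosome X. At an FPKM of at least 5, a mean of 13364 genes per library were detected, against 27058 at an FPKM of at least 1. A value of a few FPKM therefore did not separate a gene from the receptor genes.

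**Figure D2:**
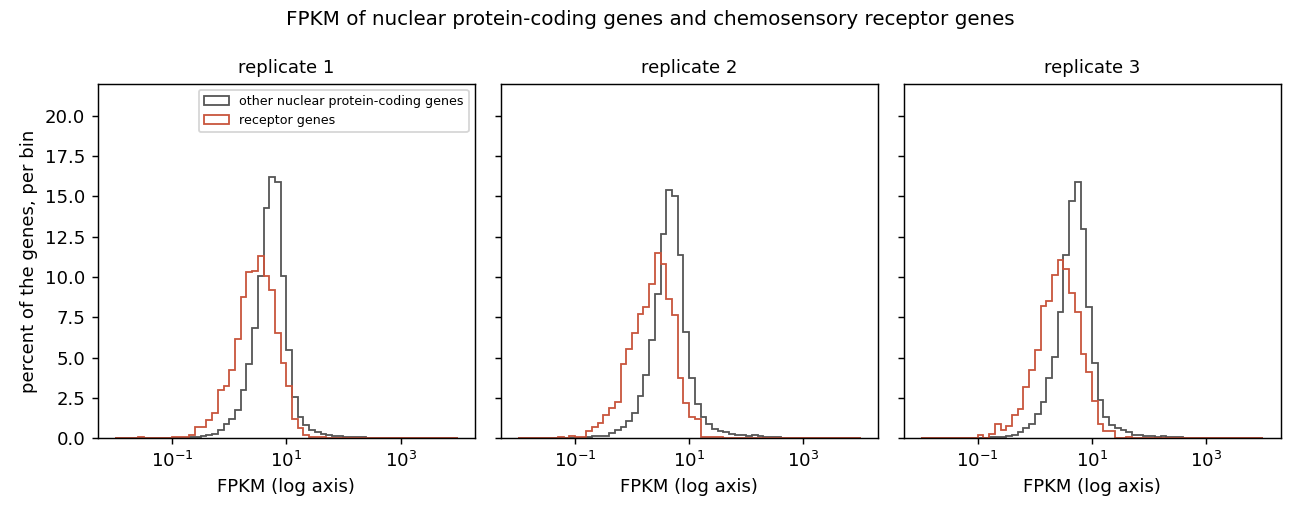
Percent of genes per bin of FPKM (log axis) in each of the 3 libraries, for chemosensory receptor genes and for the other nuclear protein-coding genes; genes at 0 are left out. The receptor medians are 2.99, 2.38 and 2.63 FPKM in replicates 1, 2 and 3, and the bulk of the coding genes overlaps with them.

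Of the named classes, 13 of 13 mitochondrial coding genes, 54 of 97 ribosomal protein genes and 2 of 1390 receptor genes (0.144%, exact 95% interval 0.0174 to 0.519) lay over 2 above the median receptor gene on the log2(FPKM + 1) scale (5.14-fold in FPKM) by limma's treat test at an adjusted p under 0.05. Over all genes 528 did (1.78%), 352 of them nuclear protein-coding (1.55% of nuclear coding genes), and 1133 at an unadjusted p under 0.05. The receptor genes' own median was the reference, and the threshold followed a look at their values, so their low share is not an independent outcome. Its interval treats genes as independent, which they are not. In simulated data 32 of 29484 genes (0.109%) drawn from the receptor genes' own spread were called. A call therefore does not set a gene apart from the highest receptor genes. These were 32 of 131 simulated calls, a share that depends on how many genes were raised and does not carry over to the 528. Ncl was 9.18 above the receptor median on the log2(FPKM + 1) scale (SE 0.46, adjusted p 0.00305, limma), Kif1c 8.41 (SE 0.36, adjusted p 0.00273) and the cytokine gene Ccl2 4.39 (SE 0.14, adjusted p 0.00273). Among translation factors 9 of 14 were called, including Pabpc1 at 345 ± 114 FPKM and Eef1a1 at 320 ± 119, and 11 adjusted over the list alone. For the cytoskeleton list this held for 10 of 15 genes, among them Cald1 at 332 ± 105 and Actb at 314 ± 135, and for 14 adjusted over the list alone. Among heat shock and unfolded protein genes 6 of 15 were called, with Hsp90aa1 at 251 ± 82.5 FPKM and the calcium-binding chaperone gene Calr at 183 ± 59.3, and 8 adjusted over the list alone. The RNA-binding protein list had 5 of 13, Ncl, Hnrnpa1, Hnrnpa2b1, Hnrnpu and Ybx1, and 6 adjusted over the list alone. This test was chosen after the data had been seen, and 4 forms of its prior variance were tried, which called 360 to 528 genes. Without replicate 3 the reported form called 0 genes (939 at an unadjusted p under 0.05), without replicate 2 it called 299, and 1036 genes lay above the 99th percentile of the receptor genes in every library.

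Among 35 gene lists fixed before the data were examined and with at least 3 measured members, 10 had medians in the highest 2.5% of 10000 random lists in every library. Mitochondrial genome genes had the highest median, 1216 ± 54.3 FPKM (SD, n = 3), with Mt-atp6, a subunit of ATP synthase, at 2204 ± 209 and Mt-cyb, cytochrome b, at 2119 ± 212. Translation factors had a median of 69.1 ± 26.8, ribosomal protein genes 63.3 ± 18.3 and cytoskeleton genes 49.2 ± 12.7. Rplp1 had 526 ± 187 FPKM, Rpl26 479 ± 162 and Rpl19 464 ± 123, with reads that processed pseudogenes can share. Heat shock and unfolded protein genes had a median of 24.4 ± 5.09 and the RNA-binding proteins 17.2 ± 5.33, with Hnrnpa1 at 272 ± 74.3. Glycolysis genes had a median of 12.5 ± 1.69, with Ldha, lactate dehydrogenase A, at 37.2 ± 8.64. The nuclear-encoded genes of oxidative phosphorylation had 9.90 ± 2.15, with Cox6c at 71.0 ± 31.5, and the antioxidant list 8.97 ± 0.515, led by the ferritin genes Fth1 at 440 ± 134 and Ftl1 at 112 ± 54.2. With CPM (counts scaled to the library total and not divided by length) in place of FPKM these last 2 lists were no longer called. Against the receptor background, limma's treat test called 1 of 14 glycolysis, 1 of 21 nuclear oxidative phosphorylation and 3 of 24 antioxidant genes. The share called over all nuclear coding genes was 1.55%. The receptor gene list was the only list called low, in the lowest 2.5% in every library. Medians of random lists of 1390 genes vary little, so this call reflects list size as well as level. The 9 pluripotency markers, with a median of 3.05 FPKM, lay between percentiles 4.73 and 14.3 and were not called.

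**Figure D3:**
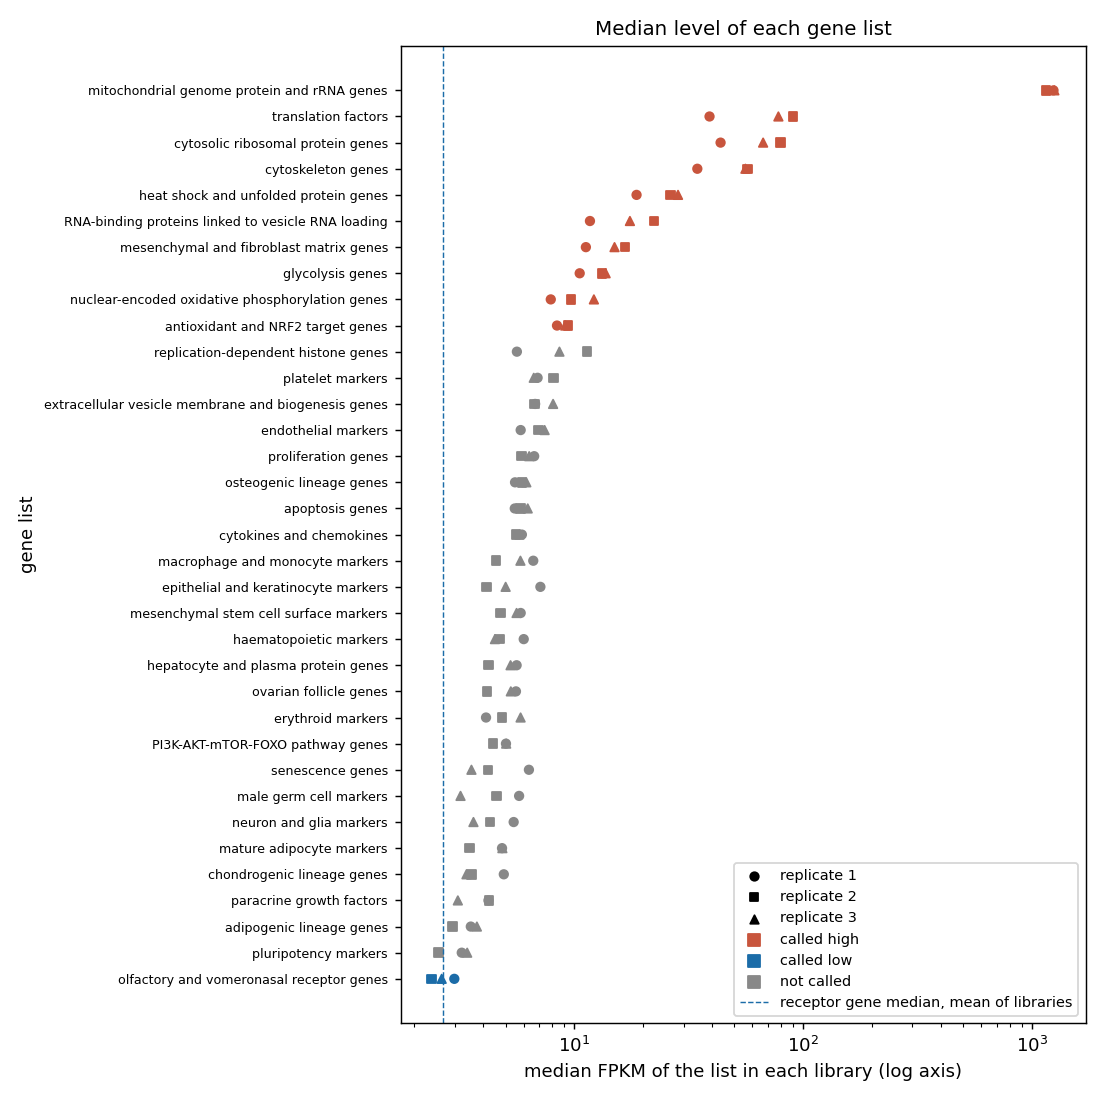
Median FPKM (log axis) of each of the 35 gene lists in each library, with marker shapes for the replicates, colours for the call against random lists and a dashed line at the mean receptor gene median, 2.67 FPKM. The 10 lists called high have mean medians from 8.97 to 1216 FPKM.

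Lists of genes that mark the source cells and other cell types were compared with random lists. The matrix and fibroblast list was called high, with a median of 14.3 ± 2.77 FPKM (SD, n = 3). Its highest member was Vim, the intermediate filament vimentin, at 172 ± 63.0, followed by Sparc at 40.6 ± 12.5, the collagen gene Col1a1 at 33.4 ± 7.69 and Tagln at 28.5 ± 4.47. Of the 20 members, 1 (Vim) was called by limma's treat test against the receptor background, and 4 adjusted over the list alone. For all nuclear coding genes the share called was 1.55%. Mesenchymal stem cell surface markers had a median of 5.39 ± 0.558 FPKM and were not called, between percentiles 66.4 and 79.3 of the random lists. Itgb1, integrin beta, was highest at 17.4 ± 4.02, while Thy1 had 7.49 ± 1.28, Cd44 6.26 ± 0.140, Nt5e 5.04 ± 0.764 and Eng 4.39 ± 1.07. Haematopoietic markers, whose cells such cultures should lack, had a median of 5.07 ± 0.817, with Cd3e at 6.97 ± 1.33 and Cd34 at 4.74 ± 0.654. On the log2(FPKM + 1) scale, the mesenchymal surface markers exceeded the haematopoietic markers by 0.08 ± 0.16, in 2 of 3 libraries, and fell at percentile 59.1 of random pairs (exact two-sided sign-flip test, p = 0.75, smallest possible 0.25). Macrophage markers had a median of 5.66 ± 1.04 FPKM, endothelial markers 6.73 ± 0.818, platelet markers 7.22 ± 0.787, erythroid markers 4.91 ± 0.859 and mature adipocyte markers 4.39 ± 0.779, and these lists were not called. Neither were epithelial (5.41 ± 1.53), hepatocyte and plasma protein (5.02 ± 0.725), neuron and glia (4.44 ± 0.914) and male germ cell markers (4.49 ± 1.28). With CPM in place of FPKM, the mesenchymal surface and the endothelial markers were called high, and without replicate 1 the endothelial markers were. CPM does not divide by length, so the CPM calls can also follow gene length.

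Lists of lineage and pluripotency genes were not told apart from random lists. Osteogenic lineage genes had a median of 5.86 ± 0.334 FPKM (SD, n = 3), chondrogenic genes 3.94 ± 0.844, adipogenic genes 3.40 ± 0.425 and pluripotency markers 3.05 ± 0.452. Pparg, the adipogenic transcription factor, had 4.68 ± 1.55 FPKM and Sp7, the osteogenic factor osterix, 7.41 ± 1.23. The osteogenic list exceeded the adipogenic list by 0.65 ± 0.14 on the log2(FPKM + 1) scale, in 3 of 3 libraries, at percentile 95.9 of random pairs (exact two-sided sign-flip test, p = 0.25, the smallest possible). Its difference from the chondrogenic list was 0.48 ± 0.30, at percentile 89.7, and neither difference was called. With CPM the latter turned to -0.17, and at a mean FPKM of at least 1 the osteogenic minus adipogenic difference was called (0.74).

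Gene groups related to the ovary and to paracrine action were measured next to these. The ovarian follicle list had a median of 5.00 ± 0.739 FPKM (SD, n = 3) and was not called. Its highest member was Inhba, which encodes the inhibin and activin beta A subunit (ENSRNOG00000014320, chromosome 17, 49095920 to 49108982), at 42.6 ± 7.89 FPKM. The other members of the list were lower, among them Gdf9 at 15.8 ± 3.39, Zp3 at 6.95 ± 0.934, Fshr at 4.70 ± 1.32, Amh at 1.97 ± 0.668 and Foxl2 at 0.276 ± 0.172. Genes of the PI3K, AKT, mTOR and FOXO pathway had a median of 4.82 ± 0.359 and were not called, with Eif4ebp1 at 19.4 ± 4.67 and Akt1 at 12.9 ± 2.87. Apoptosis genes had 5.85 ± 0.382, led by the survival gene Mcl1 at 19.9 ± 5.56. Paracrine growth factors had 3.85 ± 0.652, with Gdnf at 18.6 ± 3.48 and Tgfb1 at 13.6 ± 0.984. Cytokines and chemokines had 5.74 ± 0.167, with Ccl2, a monocyte attractant, at 76.3 ± 10.2, Cxcl1 at 31.6 ± 9.55 and Mif at 30.9 ± 7.11. Against the receptor background, limma's treat test called 1 of 21 ovarian follicle genes (Inhba) and 1 of 20 cytokines and chemokines (Ccl2). It called 0 of 24 growth factors, 0 of 22 PI3K pathway genes and 0 of 20 apoptosis genes. Over all nuclear coding genes it called 1.55%, so such counts do not set these lists apart from other genes. A gene that was not called is not shown to be absent. Growth factors lay below cytokines by a log2(FPKM + 1) difference of -0.48 ± 0.20, in 3 of 3 libraries, at percentile 3.02 of random pairs (exact two-sided sign-flip test, p = 0.25, the smallest possible), which was not called. It was called after rescaling without mitochondrial and structural RNA (-0.56), at a mean FPKM of at least 1 (-0.56) and without replicate 2 (-0.56). With CPM, which does not divide by length, the PI3K pathway list was called high.

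Vesicle membrane and biogenesis genes had a median of 7.17 ± 0.779 FPKM (SD, n = 3) and were not called, between percentiles 95.7 and 99.9. Chmp4b, a component of the membrane-cutting ESCRT machinery, had 69.6 ± 24.1, while the tetraspanin gene Cd63 had 19.4 ± 3.09 and Anxa5 12.9 ± 3.24. The list lay below the RNA-binding proteins by a log2(FPKM + 1) difference of -1.11 ± 0.45, in 3 of 3 libraries, at percentile 0.07 of random pairs, and this difference was called. Mitochondrial genome genes exceeded the nuclear-encoded oxidative phosphorylation genes by 6.82 ± 0.28 in 3 of 3 libraries, at percentile 100, and this was called. For both differences the exact two-sided sign-flip test gave p = 0.25, the smallest that 3 libraries allow. Proliferation genes had a median of 6.29 ± 0.408 FPKM, with Mki67 at 11.1 ± 1.06, and senescence genes 4.69 ± 1.46. Their difference, 0.39 ± 0.30 at percentile 89.4, was not called. Replication-dependent histone genes had 8.53 ± 2.89 and were not called, with H1f4 at 157 ± 43.6; their percentile was 76.8 in replicate 1 and 100 in replicates 2 and 3, and without replicate 1 they were called high. With CPM, which does not divide by length, or without replicate 1, the vesicle membrane list was called high.

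Agreement between the replicates was measured across genes. Across 29684 genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.796 between replicates 1 and 2, 0.797 between 1 and 3 and 0.820 between 2 and 3. It was 0.933 to 0.980 over the 528 called genes, whose call depends on level and spread. Over the 25084 genes with a symbol that were not called it was 0.726 to 0.755. The median SD of log2(FPKM + 1) was 0.36 over the called genes and 0.29 over those not called. The higher r of the called genes therefore does not mean a smaller spread. The 3 lists of 500 most abundant genes shared 384 genes, where independent lists would share 0.142. The median SD of log2(FPKM + 1) over the libraries was 0.41 for the 232 genes with a mean FPKM of at least 100 and 0.30 for all genes. Relative to replicate 1, ribosomal protein genes were higher in replicate 2 by a median log2 ratio of 0.83, in 86 of 97 genes. Mitochondrial coding genes had a median log2 ratio of -0.25 in the same comparison and receptor genes -0.37. Among genes with a symbol and a mean FPKM of at least 10, the SD of log2(FPKM + 1) was largest for the pseudogene AABR07032255.2 (2.40, 10.6 ± 14.2 FPKM). Cox7a2 (2.33, 10.2 ± 8.99 FPKM), Mir194-1 (1.95, 16.3 ± 13.3 FPKM) and the small nucleolar RNA genes LOC120101326 (1.89, 11.8 ± 14.2 FPKM) and LOC120103293 (1.83, 10.8 ± 13.8 FPKM) followed. In replicates 1, 2 and 3 these rested on few counts: 17, 103 and 0 for AABR07032255.2, and 0, 53 and 65 for Cox7a2. The counts were 18, 17 and 2 for Mir194-1, 7, 2 and 35 for LOC120101326, and 5, 2 and 31 for LOC120103293.

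Terms of the authors' annotation described the 500 most abundant genes that carry a term. By a one-sided Fisher's exact test, 76 of 2662 terms passed an adjusted p of 0.05, 31 from GO, 23 from KEGG and 22 from Reactome. The KEGG term for the ribosome held 95 of the 500 genes, against 6.05 if drawn at random (adjusted p 1.81e-84), and 63 genes of the fixed ribosomal protein list were among the 500. Targeting by the signal recognition particle, in the GO component term, held 16 genes against 0.699 (adjusted p 6.18e-16). Spliceosome genes numbered 34 against 5.44 (adjusted p 6.35e-15) and oxidative phosphorylation genes 24 against 3.21 (adjusted p 4.12e-12). Translational elongation held 11 genes against 0.459 (adjusted p 2.68e-11) and motor proteins 17 against 3.96 (adjusted p 5.31e-05). Genes of 1 family, such as those for 7SL, spliceosomal RNA and ribosomal proteins, each count as a gene, and the p-values do not allow for reads or regulation that they share. Several KEGG disease terms share the same ribosomal and respiratory genes.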

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

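No paired analysis was possible because the labels give a single group. The test against the receptor background, its settings and the class shares of counts were chosen after the data had been seen. That test depended strongly on its settings. It called 528 genes as reported, 2588 with a change over 1, 218 with a change over 3, 807 with a pseudocount of 0.1, and 1036 genes lay above the receptor 99th percentile in every library. All 4 forms of the prior variance tried were limma fits to the same values: 528, 360 (robust), 442 (single prior) and 420 (robust single prior) genes, of which 352, 221, 286 and 267 were nuclear protein-coding. Every gene called by the other 3 forms was among the 528. Leaving out a library gave 0 to 767 genes: 767 without replicate 1, 299 without replicate 2 and 0 without replicate 3 (939 at an unadjusted p under 0.05). With a single prior variance these were 477, 208 and 131. The cause was not tested.

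Shares moved with the unit. The top 10 genes held 35.1% of summed FPKM and 23.3% of counts, the top 100 51.2%, the top 1000 63.5%, and the top 10 without mitochondrial and structural RNA 5.04%. Without the 10 highest genes, 7SL-named genes held 1.15%, nuclear ribosomal RNA 1.896%, the mitochondrial genome 12.9%, ribosomal proteins 4.09% and nuclear coding genes 66.7%. Of counts these classes held 4.66%, 15.02%, 2.95%, 1.74% and 71.3%. Leaving out a library kept the nuclear coding share between 43.2% and 43.3%. Detection fell to 13364 genes per library at an FPKM of at least 5. The lowest r between replicates was 0.687 with a pseudocount of 0.1, 0.579 with 0.01 and 0.767 among genes with a mean FPKM of at least 1. The top 200 genes gave 44 terms, of which 43 were among the 76.

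Of 10 list pairs, both called differences stayed called under every alternative that gave a value; rescaling without mitochondrial RNA gives none for the mitochondrial pair. Mesenchymal minus macrophage markers turned from -0.05 to 0.86 with CPM, and osteogenic minus chondrogenic genes from 0.48 to -0.17. Leaving out a library moved mesenchymal minus macrophage markers between -0.10 and 0.0024, the latter without replicate 1, and mesenchymal minus haematopoietic markers between -0.012 and 0.14, the former without replicate 3. Growth factors minus cytokines became called after rescaling without mitochondrial and structural RNA (-0.56), at a mean FPKM of at least 1 (-0.56) and without replicate 2 (-0.56, against -0.37 without replicate 3). Osteogenic minus adipogenic genes became called at a mean FPKM of at least 1 (0.74). Of 419 calls of single lists under alternatives, 410 stayed, 7 were gained and 2 lost, the antioxidant and nuclear oxidative phosphorylation lists with CPM. Changes of pseudocount and rescaling of all genes keep the order of genes within a library, so those calls could hardly change. They count among the 410 but add no support. All changed calls came with CPM or without replicate 1. Depth limits single genes near the receptor level, where the median gene had 39 to 46 counts.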

Other observations

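The abundant long non-coding RNA genes had no symbol in the table. Among them were ENSRNOG00000063386 on chromosome 9 from 3111137 to 3112723, at 194 ± 112 FPKM (SD, n = 3; 130 without replicate 1), ENSRNOG00000066507 on the same chromosome at 184 ± 70.1 (168) and ENSRNOG00000069855 on chromosome 1 at 151 ± 23.5 (138). Mitochondrial tRNA genes held 5.59% ± 0.883 of the summed FPKM. Small nuclear RNA genes held 2.54% ± 0.458, small nucleolar RNA genes 2.35% ± 0.355 and Y RNA genes 0.510% ± 0.0231. Of the counts, mitochondrial tRNA genes held 0.223%, small nuclear 0.222%, small nucleolar 0.179% and Y RNA genes 0.0316%. The median small nuclear, small nucleolar and Y RNA gene had 1.59, 3.36 and 2.93 FPKM. Of these classes, 31 of 1303, 22 of 1599 and 3 of 16 genes were called above the receptor background, against 1.78% of all genes.

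The explanations below are hypotheses. The tests of the cell type and constant explanations, of both mitochondrial explanations and of the source cells' mRNAs were chosen only after the result was seen, and the lists for the protrusion and acidic protein hypotheses were written after the most abundant genes had been seen. No biological explanation by group was tested, since there is 1 group.

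Most genes, receptor genes included, lay at a similar low level. RNA of the source cells or of 1 other cell type as the whole cause is argued against by 8 of 8 unrelated cell type lists with medians within 2-fold of the coding median in every library, and a constant added in processing by the 39 counts of the median receptor gene in the lowest library. Genomic DNA may contribute: annotated length explained 0.640 of the variance of log2 counts among genes not called, between the bounds set beforehand of 0.3 and 0.8, so this test leaves it open. The test could not decide, since the call had left out genes of high FPKM. At similar FPKM, counts follow length whether the reads come from DNA or RNA. Covering the whole genome at the receptor density would need at least 10.5 times the table's total, a bound set beforehand to exclude uniform DNA, but that bound was wrong, since the table holds reads of annotated genes only and the outcome was fixed. Reads outside the table are not used here, so DNA stays open.

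Mitochondrial coding genes and the abundant nuclear mRNAs had different ratios between replicates 2 and 1. The mitochondrial median log2 ratio of replicate 2 to replicate 1 lay -1.01 from that of the called nuclear coding genes, with a spread of 0.14 over the 13 genes and 0.54 over the called genes. For replicate 3 to replicate 1 the medians were -0.059 for mitochondrial coding and 0.62 for called nuclear coding genes. Both ratios share replicate 1 and restate the pattern, so transcripts that vary together with those mRNAs stay open. For replicate 2 to replicate 1, the mitochondrial median lay 0.126 from that of the receptor genes (-0.25 against -0.37), but closer still to nuclear coding genes not called (-0.20), long non-coding (-0.26), small nuclear (-0.25) and miRNA precursor genes (-0.27), so this does not point to mitochondrial DNA and leaves it open. The mitochondrial ribosomal RNA genes had a median ratio of 0.74, near the 0.76 of the called nuclear coding genes. For replicate 3 to replicate 1 these medians were further apart, at 0.29 and 0.62. The pattern rests on called genes, of which 0 were left without replicate 3.

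Some mRNAs lay far above the rest, among them Kif1c, Rab13, Net1 (335 ± 80.9 FPKM), Trak2 (215 ± 77.4) and Kctd10, reported in other cells at protrusions, and Ncl and Anp32b, which encode proteins with long acidic stretches. Among members whose values had not been seen, the 4 protrusion mRNAs had a median at percentile 99.97 of random coding lists and the 16 acidic protein genes at percentile 100, so either property may go with a higher level. Over the whole lists 7 of 11 and 13 of 29 members were called by limma, but the called members were those already seen when the lists were written, and the unseen members had medians of 23.8 and 15.2 FPKM. Housekeeping lists such as the cytoskeleton genes also reached percentile 100, so neither test separates the hypothesis from general abundance in the cells. Whether these are the source cells' most abundant mRNAs stays open, since no RNA of the cells was analysed here. A comparison with the matrix list (at most 0.0349 of the lowest of the 10 most abundant mRNAs with a symbol) cannot decide it, since it uses the pattern's own top genes.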
